A study of Mus musculus with 4 samples.

How the data were processed

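RNA of ZHBTc4 mouse embryonic stem cells was measured on 4 two-colour Agilent arrays of design 014868. Per the labels' protocols, cells came off embryonic fibroblast feeders, were passaged 2 times on gelatin and were treated for 48 h with 2 µg doxycycline, with or without TCP. Total RNA was extracted with Trizol and 1 µg was labelled from an oligo-dT primer, per the labels. The dyes come from the labels: Cy5 held the treated cells and Cy3 the ZHBTc4 reference on every array, with no dye swap.

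Spot and local background values are intensities on a linear scale as scanned, made with Agilent Feature Extraction 10.1.1.1 and annotated on mouse mm7 (NCBI35), per the file headers. The log10 ratios of Cy5 over Cy3 in the same files were background-subtracted and dye-normalized by that software with a linear and lowess step, per the file headers. The authors' deposited series matrix holds log10 values that matched those ratios for each spot within 0.005, so scale and direction are settled; the medians of its columns were 0, 0.0111, 0 and 0. Further upstream steps are not given in the sources used here.

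Each array held 45018 spots, of which 1639 control spots were left out after background correction and had weight 0 in the loess fit. Mean spot signals were corrected with limma's normexp (offset 50) on median local backgrounds, followed by loess within each array. One step departs from the design written before the data were examined. Local backgrounds over 2 times the array's median in that channel, 11 to 112 spots per array and channel, were replaced by that median. As read, the brightest background on dox replicate 1 was 12750 times the median in Cy5 and the normexp fit gave a background SD of 9301 there, against 2.41 after replacement. The fit as written is reported as an alternative beside the counts, as are limits of 5 and 10 times the median. The limits of 2, 5 and 10 times were chosen after seeing the data. Spots with non-uniformity or population outlier marks, 119 to 176 per array, were set to missing.

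The 43379 other spots held 41174 probes, and spots of 1 probe were averaged. A probe was tested where it was well above background on both arrays of a group in Cy5 or on all 4 arrays in Cy3, which left 31114 probes and 21411 genes. A gene was represented by its brightest tested probe; another called probe of the gene had the opposite sign for 15 genes with dox and 22 with dox+TCP. Symbols were updated through a table of the assembly GRCm38.p6, used for names only: 22951 probes matched by accession, 6659 by symbol and 3109 by synonym, and 8455 kept the name in the files.

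limma was fitted with a mean per group over all 4 arrays, which share 1 estimate of the spread (2 residual degrees of freedom, 1.79 prior degrees of freedom), with eBayes moderation and Benjamini-Hochberg adjustment at 0.05. Each group mean was tested against 0 and the groups against each other. Both comparisons with the reference share it, so their calls were not compared. The replicates are biological per the labels.

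23 gene lists were fixed before the data were examined: pluripotency, trophoblast, primitive endoderm, mesoderm and primitive streak, neuroectoderm, fibroblast markers of feeder cells, LSD1 and partner complexes, histone methylation and enhancer cofactors, monoamine metabolism, two-cell-like, germline, REST-repressed neuronal, p53 response, amino acid and integrated stress response, oxidative stress response, sterol biosynthesis, cell cycle, glycolysis and hypoxia, epithelial, mesenchymal transition, interferon response, imprinted and housekeeping genes. They were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The named genes follow a rule fixed then too: per comparison the 10 largest rises and 10 largest falls among called genes with 1 direction on every array and a name other than a clone or predicted transcript. Where none was called, the rule took the 10 each way with the smallest unadjusted p. It adds Pou5f1, Kdm1a, Maoa and Maob, and up to 4 members of each list by adjusted p. Some genes that the rule takes are not reported here. Genes named outside it are said to be chosen after their values were seen.

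On simulated data with 21348 genes and 200 changed, limma recovered 76.5% of genes changed by 2 on the log2 scale for dox against the reference, with 4.375% false among 160 called, and 0% of those changed by 1. For dox+TCP against dox it recovered 43.5% at 2, with 1.136% false among 88 called, and 0% at 1. A gene that did not pass can therefore have changed by 1 on that scale. With only 200 genes changed, the adjusted threshold was stricter than in the real comparisons with the reference. For dox, 3122 genes were called, and 570 higher and 928 lower ones changed by at least 2-fold, so smaller changes were also called. The 0% is therefore not the recovery of that test on the real data.

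Alternatives were no background subtraction, a normexp offset of 16, the scanner's log ratios, the series matrix values, median centring, quantile scaling of average intensities between arrays, no filter or a stricter filter on dim probes, the mean of a gene's probes, outlier spots kept, an intensity trend in eBayes, and each array left out. Others were scan day as a block, slide as a random block (correlation 0.658, fitted with statmod), the replicate number as a block, a group's arrays alone, the Cy5 channel alone, a 2-fold minimum, an estimated correlation in camera, and fry. Slide as a fixed block leaves no residual degrees of freedom, so values within slide 1 are given instead. Slide 1 held replicate 1 of both groups, and 3 arrays shared a scan day, without dox+TCP replicate 2. Scan day as a block therefore has in effect the same fit as leaving out dox+TCP replicate 2. It does not adjust the other arrays for scan day. Versions were R 4.3.3, limma 3.58.1, data.table version 1.17.8, statmod 1.5.0, jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9.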

Results

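Gene expression was measured in ZHBTc4 cells, a mouse embryonic stem cell line in which doxycycline shuts off the transgene that supplies Oct4 (Pou5f1), the transcription factor that keeps these cells undifferentiated. Loss of Oct4 turns such cells toward trophoblast, the lineage that forms the placenta. The study's title asks about LSD1 (Kdm1a), a histone demethylase, during differentiation of embryonic stem cells. Cells were treated for 48 h with doxycycline alone (dox, which the labels title as the control) or with doxycycline and TCP (dox+TCP), with 2 biological replicates each per the labels. The labels abbreviate TCP and do not spell it out; in work on LSD1 the abbreviation usually stands for tranylcypromine, an inhibitor of LSD1 and of the monoamine oxidases. Each of the 4 arrays carried treated cells in Cy5 and ZHBTc4 cells with no treatment named, the reference, in Cy3.

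The median Cy5 signal was 249 and 213 on dox replicates 1 and 2 and 224 and 239 on dox+TCP replicates 1 and 2, against median local backgrounds of 57, 60, 56 and 53.5. In Cy5, 76.4%, 76.7%, 78.1% and 74.3% of the non-control spots were well above background, and in Cy3 75.0%, 78.1%, 77.2% and 68.8%. No non-control spot was saturated (0 in either channel). After probes were reduced to genes, 21411 genes were tested. The number of arrays limits the precision of every value: the median SE of a group's log2 ratio was 0.114 and that of a difference between the groups was 0.161. Across genes, which are not independent replicates, log2 ratios correlated at 0.662 between the dox replicates and 0.865 between the dox+TCP replicates, and at 0.878 between the replicate 1 arrays of both groups, which shared a slide. The reference was ZHBTc4 cells on each array per the labels and was counted as 1 control sample. Its expression was not the same on each array, as described below for trophoblast genes. Cy3 levels correlated across genes at 0.999 between the replicate 1 arrays and at 0.982 to 0.989 for the other pairs. Differences between the reference channels of the arrays enter the log ratios and their spread, and the spread of the control is not estimated apart from that. Dyes were not swapped, so gene-specific dye bias stays in both comparisons with the reference and cancels between dox+TCP and dox.

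Doxycycline for 48 h, compared with the reference, addresses which genes change as Oct4 is lost. Every treated sample had both doxycycline and the loss of Pou5f1, so effects of the drug itself cannot be told apart from those of the loss. Differences in culture from the reference, for which the labels name no treatment, cannot be told apart either. Of the measured genes, 34 of 43 pluripotency genes fell, and 15 of 31 sterol synthesis genes, 14 of 34 epithelial genes and 5 of 46 trophoblast genes rose, while 1 epithelial and 2 trophoblast genes fell. As lists, none of these 4 held in camera with an estimated correlation (adjusted p = 0.299, 0.299, 0.557 and 0.648). That setting rests on the 2 residual degrees of freedom, so few lists could pass it at any correlation. The sterol estimate of 0.00172 lay below the preset 0.01, and the call was still lost. By fry, the pluripotency, sterol and epithelial lists passed (adjusted p = 0.0046, 0.0117 and 0.0441) and the trophoblast list did not (0.228). Pou5f1 itself fell by 3.50 ± 0.10 on the log2 scale (SE, n = 2 arrays; −3.38 and −3.62), with a limma adjusted p of 0.0105. The deepest fall was that of Nr0b1, an orphan nuclear receptor of the pluripotency network, at −5.75 ± 0.11 (limma adjusted p = 0.0105). The largest rise was that of Fabp3, a fatty acid carrier, at 4.09 ± 0.52 (limma adjusted p = 0.0264). In the mm7 (NCBI35) coordinates of the files, the Pou5f1 probe (NM_013633) lies on chromosome 17 from 33612047 to 33612107, the Nr0b1 probe (NM_007430) on chromosome X from 81582482 to 81582541, and the Fabp3 probe (NM_010174) on chromosome 4 from 129760011 to 129760070.

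limma called 3122 of the 21411 genes, 1354 higher and 1768 lower, of which 570 and 928 changed by at least 2-fold. At an unadjusted p under 0.05 there were 7017 genes, where chance alone gives 1070.55. Of the called genes, 35 were not well above background in the treated cells and 20 in the reference, so their size is only a bound. Other large falls were those of the junction protein gene Jam2 (−4.67), Msln (−4.45), Crocc2 (−4.38, well above background in Cy5 on 1 of the 2 arrays), the lymphatic growth factor gene Vegfc (−4.30), the neuronal gene Stmn2 (−4.18), Calca (−4.06), the threonine dehydrogenase gene Tdh (−4.03) and Chrna9 (−3.90). After Fabp3, the largest rises were those of Mogat2, an acyltransferase of triglyceride synthesis (2.76), the epithelial splicing factor gene Esrp2 (2.75), S100a13 (2.74), the transcription factor gene Cebpb (2.70), Cmtm8 (2.69), Rgma (2.66), Emp2 (2.63), Mbp (2.60) and Aldh3b2 (2.56). Kdm1a stood at 0.25 (limma adjusted p = 0.151), Maoa at −0.30 (0.269) and Maob at 0.42 (0.161), so none of these 3 passed. Median centring in place of loess moved the median of all genes by 0.18, put Kdm1a at 0.96 (limma adjusted p = 0.0154, in a range from 0.0154 to 0.45 over the alternatives) and called 4885 genes higher and 1136 lower, 81.13% higher against 43.37%. With the local backgrounds exactly as read, the setting written before the data were examined, limma called 0 genes (1811 at an unadjusted p under 0.05); a few bright backgrounds disturbed that correction and were replaced in the values given here, a step chosen after the data were seen. The calls also rest on the spread shared with the dox+TCP arrays: the count was 0 from the dox arrays alone. In that fit 5138 genes had an unadjusted p under 0.05, so the 0 does not show that no gene changed. Leaving out either dox+TCP array, or scan day as a block, takes the spread from those same dox arrays, so these are not separate checks.

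Of 43 measured pluripotency genes, 34 fell, 9 did not pass and 0 rose, and 37 fell and 1 rose when adjusted over the list alone. They included the co-receptor gene Tdgf1 (−3.42), Foxd3 (−3.28), Sox2 (−2.87), Esrrb (−2.72), the signalling gene Nodal (−2.62) and Klf4 (−2.22), and Nanog fell less (−1.10); Sox2 and Nanog were chosen after their values were seen. The list's median was −1.74 (limma camera adjusted p = 7.57e-17; adjusted p = 0.299 with an estimated correlation). Of 12 two-cell-like genes, which mark a rare early-embryo-like state in stem cell cultures, 7 fell and 0 rose (8 and 0 adjusted over the list alone), among them Zscan4c (−2.94), Tcstv3 (−2.29) and Tcstv1 (−2.18). That list's median was −1.41 (camera adjusted p = 0.000116; adjusted p = 0.362 with an estimated correlation).

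**Figure D1:**
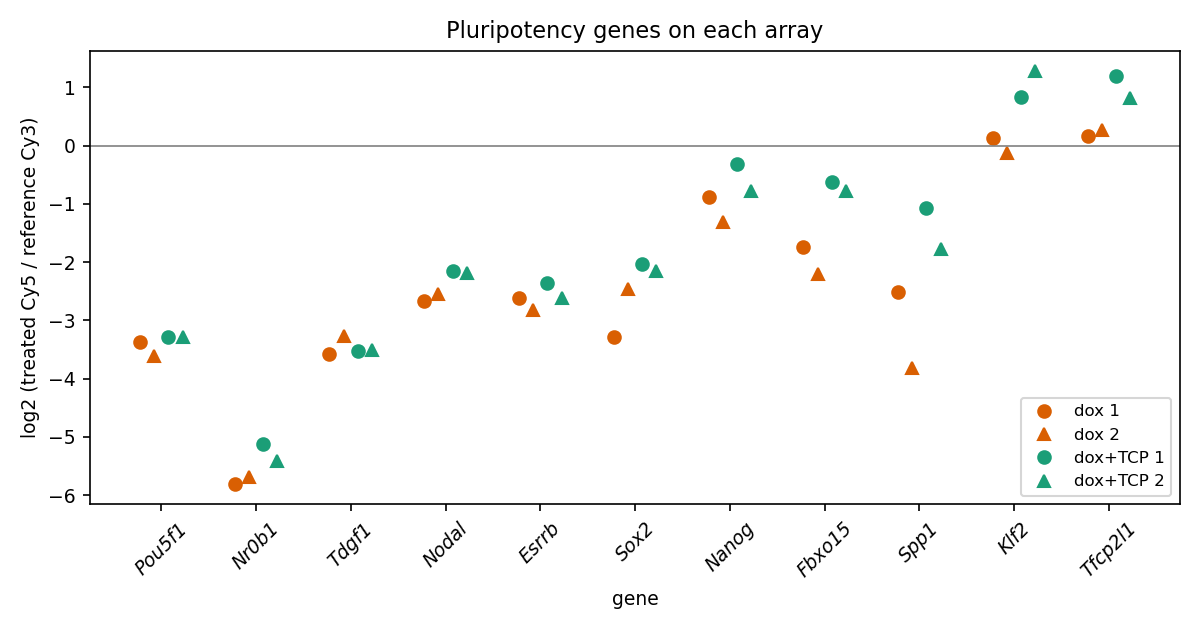
The log2 ratio of treated cells to the reference is plotted for 11 pluripotency genes, chosen after their values were seen, with a point for each array. Pou5f1 lies at −3.38 and −3.62 on the dox arrays and at −3.29 and −3.28 on the dox+TCP arrays.

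Trophoblast genes were higher as a list, with a median of 1.14 over 46 genes (camera adjusted p = 0.000116; adjusted p = 0.648 with an estimated correlation), but the replicates differed. 5 members rose: the growth factor gene Igf2 (2.48), the homeobox gene Msx2 (2.21), H19 (1.66), Bmp8b (1.46) and Cited1 (1.28). Igfbp3 (−1.37) and Ddah1 (−1.18) fell, and 11 rose and 2 fell when adjusted over the list alone. The median of the list was 1.66 on dox replicate 1 and 0.44 on dox replicate 2. The keratin genes Krt8 (3.94 and 0.56 on the 2 arrays) and Krt18 (4.75 and 1.44) and the trophoblast regulator Cdx2 (3.39 and 0.73), all chosen after their values were seen, did not pass (limma adjusted p = 0.27, 0.161 and 0.252). In the reference channel these genes were already brighter on the replicate 2 arrays. Krt8 stood at 13.03 and 13.35 (normalized log2 Cy3 intensity) on the replicate 1 arrays and at 16.45 and 16.56 on the replicate 2 arrays, while its Cy5 level lay between 16.28 and 17.01 on all 4. Over the list, 41 of 46 members were brighter in the reference of replicate 2, by a median of 0.616, and the Cy5 difference was 0.030.

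**Figure D2:**
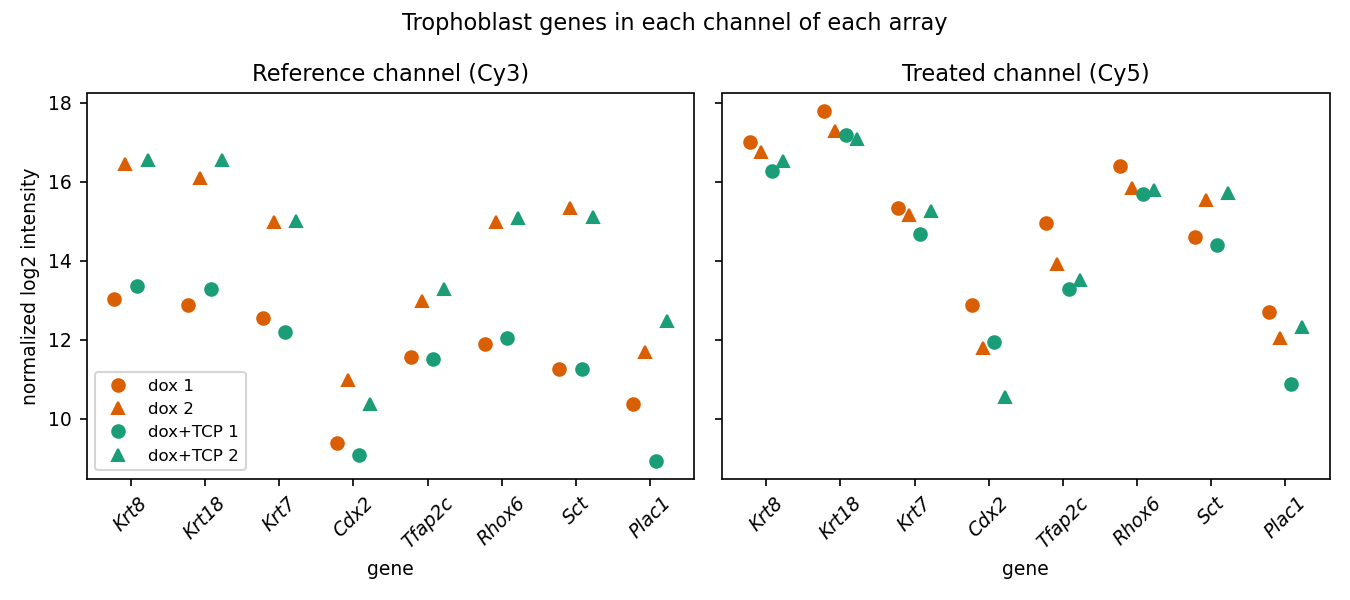
Normalized log2 intensities of trophoblast genes are plotted per array for the treated cells (Cy5) and the reference (Cy3). Krt8 differs between replicate 1 and replicate 2 in the reference channel, 13.03 against 16.45 for the dox arrays, and little in the treated channel, 17.01 against 16.75.

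Epithelial genes rose in 14 of 34 cases and fell in 1, or 18 and 4 adjusted over the list alone. Esrp2 (2.75), the tight junction genes Tjp3 (2.34) and Cldn3 (2.25) and the transcription factor gene Ovol2 (1.08) rose, and Rab25 (−0.53) fell. The median was 0.99 (camera adjusted p = 5.23e-06; adjusted p = 0.557 with an estimated correlation), 1.13 on dox replicate 1 and 0.54 on dox replicate 2. In all, 29 of the 34 were brighter in the reference of replicate 2, by a median of 0.477, and median centring put the list's ratio at 1.52. Sterol and fatty acid synthesis genes rose in 15 of 31 cases and fell in 0 (17 and 1 adjusted over the list alone), with Dhcr7 (1.61), Fdps (1.22), Insig1 (1.19) and Fads1 (1.07) as examples. Their median was 0.62 (camera adjusted p = 5.12e-07; adjusted p = 0.299 with an estimated correlation), and 1.28 under median centring. Housekeeping genes had a median of 0.20 and 5 of 29 rose, 9 rising and 3 falling adjusted over the list alone, including Rpl13a (1.13) and Rps18 (0.75). The camera adjusted p was 0.016 for the housekeeping list (adjusted p = 0.557 with an estimated correlation), and it was 0.256 with the scanner's own log ratios, where the median was 0.13. The housekeeping median was 0.89 under median centring and 0.32 without dox replicate 1.

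Cell cycle genes fell in 6 of 36 cases and rose in 0 (7 and 0 adjusted over the list alone), led by the cyclin gene Ccnd1 (−2.13), with Cdc20 (−0.85), Ccne1 (−0.78) and the replication gene Mcm2 (−0.62). Their median was −0.46 (camera adjusted p = 0.000344; adjusted p = 0.557 with an estimated correlation) and turned to 0.25 under median centring, as Mcm2 did to 0.06. It was −0.21 on dox replicate 1 and −0.63 on dox replicate 2. Histone methylation and enhancer cofactor genes had a median of −0.35 (0.25 under median centring); 6 of 31 fell and 1 rose, over all genes and adjusted over the list alone, among them Eed (−1.26), Ash2l (−1.23), Dpy30 (−1.14) and Kdm5b (−0.94). The camera adjusted p for the cofactor list was 0.016 (adjusted p = 0.557 with an estimated correlation). It was 0.0516 without dox replicate 2, where the median was −0.18, 0.0658 with the mean of a gene's probes and 0.356 under median centring. Mesenchymal genes had a median of −0.32 that turned to 0.16 under median centring; 6 of 29 fell and 1 rose (9 and 4 adjusted over the list alone), with Twist1 (−1.45), Snai2 (−1.29) and Mmp2 (−1.18) lower and Ccn1 (1.26) higher. That list's camera adjusted p was 0.0442 (adjusted p = 0.648 with an estimated correlation). The median was −0.72 on dox replicate 1 and −0.27 on dox replicate 2, and the call was lost in 9 of 23 alternatives. The camera adjusted p was 0.397 without dox replicate 1 and 0.0507 without either dox+TCP array. The fibroblast markers of feeder cells stood at −0.54 and 0.025 on the same arrays, and both lists were dimmer in the reference of replicate 2, by medians of −0.472 (mesenchymal) and −0.570 (fibroblast).

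Neuronal genes that REST represses fell in 7 of 30 cases and rose in 0, over all genes and adjusted over the list alone. They were led by Stmn2 (−4.18) and the neurofilament genes Nefh (−2.85), Nefl (−2.64) and Nefm (−1.65). The median was −0.12 (camera adjusted p = 0.00551; adjusted p = 0.648 with an estimated correlation). It was −0.20 on dox replicate 1 and −0.057 on dox replicate 2, with a camera adjusted p of 0.162 without dox replicate 1. Neuroectoderm genes fell in 5 of 23 cases and rose in 0 (6 and 1 adjusted over the list alone), including Gbx2 (−3.28), Pou3f1 (−2.09), Tubb3 (−1.28) and En2 (−1.05). Their median was −0.14 (camera adjusted p = 0.0239; adjusted p = 0.648 with an estimated correlation). It was −0.23 on dox replicate 1 and −0.031 on dox replicate 2, with a camera adjusted p of 0.219 without dox replicate 1, and −0.040 under median centring. With the local backgrounds as read, the neuroectoderm, REST and mesenchymal lists did not pass (camera adjusted p = 0.375, 0.361 and 0.191), and the pluripotency, two-cell-like, trophoblast and epithelial medians were −1.13, −0.92, 0.50 and 0.52. In all, camera called 11 of the 23 lists, 4 higher and 7 lower, and 0 with an estimated correlation. Over the alternatives run, the camera adjusted p ranged from 1.74e-05 to 0.557 for housekeeping genes and from 4.71e-05 to 0.876 for cell cycle genes. It reached 0.557 for the cofactor list and 0.648 for the mesenchymal, REST and neuroectoderm lists, from lowest values of 0.000373, 0.00168, 7.52e-05 and 0.00385.

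The other 12 lists did not pass as lists, although members did. Medians and camera adjusted p were −0.04 and 0.953 for primitive endoderm, −0.16 and 0.0971 for mesoderm and primitive streak, and −0.21 and 0.0729 for the fibroblast markers of feeder cells. They were 0.21 and 0.142 for LSD1 and partner complexes, 0.13 and 0.438 for monoamine metabolism, −0.29 and 0.142 for germline genes, 0.10 and 0.158 for the p53 response, and 0.12 and 0.0715 for the amino acid and integrated stress response. For the oxidative stress response, glycolysis and hypoxia, the interferon response and imprinted genes they were 0.05 and 0.379, 0.17 and 0.374, 0.18 and 0.374, and −0.11 and 0.974. Without dox replicate 2 the fibroblast list passed at −0.54 (camera adjusted p = 9.66e-05) and the p53 response at 0.29 (0.0421), and without dox replicate 1 they stood at 0.025 and 0.0043. The amino acid list passed at 0.16 without dox replicate 1 (0.00513), primitive endoderm turned to 0.037 without dox replicate 1 and imprinted genes to 0.062 without dox replicate 2. Without dox replicate 2 the medians were 0.10 for LSD1 and partner complexes, 0.039 for monoamine metabolism, −0.15 for germline genes, 0.0060 for the oxidative stress response, 0.049 for glycolysis and hypoxia and 0.055 for the interferon response. Without dox replicate 1 they were 0.29, 0.22, −0.32, 0.11, 0.21 and 0.17, and these 6 lists did not pass in either case. Over the alternatives run, the camera adjusted p ran from 9.66e-05 to 0.78 for fibroblast markers, from 0.00481 to 0.76 for the p53 response and from 0.00455 to 0.689 for the amino acid list. LSD1 and partner complexes, the oxidative stress response and glycolysis and hypoxia each passed in 1 of 23 alternatives (lowest camera adjusted p = 0.0117, 0.0117 and 0.0205). Their highest medians over the alternatives were 0.75, 0.57 and 0.67. Single members included the LSD1 partner genes Rcor2 (−1.56) and Ctbp2 (−1.72), which fell, and Mta3 (0.95), which rose. The glucose transporter gene Slc2a3 (2.35) and the p53 target Cdkn1a (1.02) rose, and the amino acid transporter gene Slc7a3 (−3.58) and the glutathione transferase gene Gsta3 (−3.67) fell.

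Doxycycline with TCP, compared with the reference, shows which genes differ from the same reference when TCP is present as well. Pou5f1 fell by 3.29 ± 0.10 on the log2 scale (SE, n = 2 arrays; limma adjusted p = 0.0146), and 26 of 43 pluripotency genes fell and 2 rose (adjusted p = 0.288 for the list with an estimated correlation). Nr0b1 again had the deepest fall (−5.27 ± 0.11, limma adjusted p = 0.0146) and Fabp3 the largest rise (4.99 ± 0.52, limma adjusted p = 0.0209). In their lists, 16 of 31 sterol genes, 7 of 29 p53 genes and 7 of 32 genes of the amino acid and integrated stress response rose, and 2 of the last fell. These list calls were lost in camera with an estimated correlation (adjusted p = 0.288, 0.463 and 0.69), a setting that rests on 2 residual degrees of freedom. By fry, the sterol and p53 lists passed (adjusted p = 0.0065 and 0.0187) and the amino acid list did not (0.189).

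limma called 3297 genes, 1565 higher and 1732 lower, of which 676 and 800 changed by at least 2-fold, and 7107 had an unadjusted p under 0.05. Of the called genes, 31 were not well above background in the treated cells and 22 in the reference. The rises after Fabp3 were S100a13 (3.33), the stress-induced transcription factor gene Ddit3 (3.27), Adssl1 (3.22), Zfp773 (3.11), Emp2 (2.93), Rab11fip1 (2.92), Mbp (2.82), Mogat2 (2.80) and the peptide transporter gene Slc15a2 (2.79). The falls after Nr0b1 were Jam2 (−4.34), Crocc2 (−4.10, well above background in Cy5 on 1 of the 2 arrays), Skor1 (−3.86), Stmn2 (−3.78), Vegfc (−3.74), the MAP kinase phosphatase gene Dusp6 (−3.62), Calca (−3.60), Tdgf1 (−3.52) and Tdh (−3.51). Kdm1a (0.04), Maoa (−0.42) and Maob (0.25) did not pass (limma adjusted p = 0.81, 0.15 and 0.348). Median centring moved the median of all genes by 0.14 and called 4002 genes higher and 1107 lower, 78.33% higher against 47.47%. With the local backgrounds as read, limma called 0 genes (1908 at an unadjusted p under 0.05), and it called 0 without either dox+TCP array or with scan day as a block and 5936 without either dox array.

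Of the 43 pluripotency genes, 26 fell and 2 rose (35 and 2 adjusted over the list alone), with a median of −1.41 (camera adjusted p = 8.72e-16; adjusted p = 0.288 with an estimated correlation). The 2 that rose were Klf2 (1.06) and Tfcp2l1 (1.00); another called probe of Klf2 had the opposite sign, and Tfcp2l1 was chosen after its value was seen. Two-cell-like genes fell in 6 of 12 cases and rose in 0 (7 and 0 adjusted over the list alone), with a median of −0.91 (camera adjusted p = 0.000465; adjusted p = 0.413 with an estimated correlation). Zscan4c stood at −1.86 and Tcstv3 at −1.27 among them. Trophoblast genes had a median of 0.77 (camera adjusted p = 0.000465; adjusted p = 0.69 with an estimated correlation), with 5 of 46 rising and 1 falling (4 and 1 adjusted over the list alone), including Cited1 (1.90), Msx2 (1.90) and Bmp8b (1.88). The medians of that list on the 2 arrays were 1.21 and 0.29, with the brighter reference on replicate 2 described for the dox arrays.

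Sterol genes rose in 16 of 31 cases and fell in 0 (20 and 1 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 2.79e-07; adjusted p = 0.288 with an estimated correlation). Dhcr7 (1.85), Fads2 (1.75), Fads1 (1.52) and Fdps (1.31) were among them. In the p53 list 7 of 29 rose and 0 fell (9 and 1 adjusted over the list alone): Cdkn1a, an inhibitor of the cell cycle (1.80), Ccng1 (1.27; 0.74 as the mean of its probes, with a limma adjusted p of 0.111 in a range from 0.0092 to 0.352), the pro-apoptotic Bbc3 (1.19) and Ddit4 (0.65) were examples. The median was 0.28 (camera adjusted p = 0.0256; adjusted p = 0.463 with an estimated correlation), 0.54 without dox+TCP replicate 2, 0.62 under median centring and 0.38 with the mean of a gene's probes, where the camera adjusted p was 0.0741. In the amino acid and integrated stress response, 7 of 32 rose and 2 fell (16 and 3 adjusted over the list alone), with Nupr1 (1.97) and Atf3 (1.12) higher and Slc7a3 (−3.27) lower. Its median was 0.32 (camera adjusted p = 0.0116; adjusted p = 0.69 with an estimated correlation), 0.84 under median centring and 0.25 without dox+TCP replicate 2, where the camera adjusted p was 0.0848. Epithelial genes rose in 6 of 34 cases, as Cldn3 (2.20), Tjp3 (2.04) and Ovol2 (1.32) did, and fell in 4: Grhl2, a regulator of epithelial identity (−1.33), Jup (−0.98), Pkp3 (−0.77) and Rab25 (−0.61). Adjusted over the list alone, 8 rose and 5 fell. The epithelial median was 0.56 (camera adjusted p = 0.0325, and 0.69 with an estimated correlation). It was 0.30 without dox+TCP replicate 1 and reached 0.93 over the alternatives, and the call was lost in 3 of 23 of them.

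Cell cycle genes fell in 8 of 36 cases and rose in 0 (9 and 0 adjusted over the list alone), including Ccnd1 (−1.75), Ccne1 (−1.11) and Mcm5 (−0.91). Their median was −0.52 (camera adjusted p = 3.06e-06; adjusted p = 0.463 with an estimated correlation), and −0.03 under median centring (camera adjusted p = 0.0798). Histone methylation and enhancer cofactor genes had a median of −0.33 (0.07 under median centring), and 6 of 31 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000583; adjusted p = 0.463 with an estimated correlation). Neuronal genes that REST represses had a median of −0.12, with 7 falling and 0 rising, also adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.69 with an estimated correlation). Neuroectoderm genes had a median of −0.06, with 5 falling and 0 rising, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0407; adjusted p = 0.69 with an estimated correlation). That median was −0.16 on dox+TCP replicate 1 and −0.031 on dox+TCP replicate 2. The camera adjusted p was 0.115 without dox+TCP replicate 1 and 0.0537 and 0.0536 without dox replicates 1 and 2. With the local backgrounds as read the REST and neuroectoderm lists did not pass (0.148 and 0.102), and the two-cell-like median was −0.30. Over the alternatives run, the camera adjusted p ran from 0.000693 to 0.463 for p53 genes, from 0.00153 to 0.69 for the amino acid list and from 0.00614 to 0.69 for neuroectoderm genes. Camera called 11 lists, 5 higher and 6 lower, and 0 with an estimated correlation. Its adjusted p ranged over the alternatives from 0.00621 to 0.69 for epithelial genes and from 6.59e-09 to 0.463 for cell cycle genes. The other lists had camera adjusted p values between 0.0848 for mesoderm and primitive streak (median −0.18; −0.19 over the 23 of 24 members with a value on every array, which camera tested) and 0.947 for glycolysis and hypoxia (median 0.08). Without dox+TCP replicate 1 these medians were −0.12 and 0.028, and without dox+TCP replicate 2 −0.16 and 0.13. Some of these lists passed in other alternatives. Housekeeping genes (0.14, camera adjusted p = 0.115) reached a median of 0.70 and a lowest adjusted p of 0.00059. The oxidative stress response (0.08, 0.395) reached 0.49 and 0.0179, and mesoderm and primitive streak a lowest adjusted p of 0.0157.

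The comparison of dox+TCP with dox asks what TCP adds when Oct4 is shut off, and here the dye bias cancels. No single gene passed the test. The pluripotency and two-cell-like lists were higher and the epithelial list and the list of LSD1 and its partners were lower, by medians from −0.34 to 0.30 on the log2 scale. These 4 calls were lost in camera with an estimated correlation (adjusted p = 0.408 for each), which rests on 2 residual degrees of freedom. They were also lost with fry (adjusted p = 0.61, 0.217, 0.748 and 0.686). Pou5f1 stood 0.21 ± 0.14 higher (SE, n = 2 arrays per group) and Kdm1a at −0.21, and neither passed (limma adjusted p = 0.996 for both); Maoa stood at −0.12 and Maob at −0.17.

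limma called 0 of 21411 genes, with a smallest adjusted p of 0.996. At an unadjusted p under 0.05 there were 946 genes, 586 higher and 360 lower, against 1070.55 by chance if the arrays are independent. The count was also 0 with the replicate number as a block (1623 unadjusted), with slide as a random block (2385), in the Cy5 channel alone (304) and with the local backgrounds as read (459). The unadjusted counts of 1623 and 2385 lay above 1070.55, and those of 304 and 459 lay below it. The arrays of the groups did not overlap for 7071 genes, 33.12% against 33.33% by chance if the arrays are exchangeable. Deviations of same-numbered arrays correlated at 0.472 across genes in log2 ratios. The chance figures leave this out, so they cannot show whether fewer genes differed than chance gives. An exact permutation test of 2 against 2 arrays cannot go below a p of 1 in 3. On simulated data, limma recovered 43.5% of genes changed by 2 on the log2 scale in this comparison and 0% of those changed by 1. The genes with the smallest unadjusted p, none past the threshold, were led by Mme, a cell-surface peptidase, at 1.76 ± 0.11 (limma adjusted p = 0.996), which stood at −1.45 and −1.38 against the reference on the dox arrays and at 0.35 and 0.34 on the dox+TCP arrays. Others with higher values were Ly6c1 (1.72), Glod5 (1.37), Myom2 (1.32), Mylpf (1.27), Zfp773 (1.22), Anxa8 (1.04), Gask1b (0.93), Prps1 (0.91) and Aopep (0.88). Lower values were those of Chst5 (−1.13), Rgma (−1.03), Kdf1 (−0.91), Pex2 (−0.90), Adnp (−0.88), the nuclear export factor Nxf1 (−0.77), the DNA demethylation enzyme Tet3 (−0.76), Tmem185b (−0.70) and Mbd2, a methyl-CpG binding protein of the NuRD complex (−0.67).

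Pluripotency genes had a median difference of 0.21 (camera adjusted p = 0.000608, and 0.408 with an estimated correlation). Spp1 stood at 1.75, Fbxo15 at 1.28 and Klf2 at 1.05, none past the threshold. For dox+TCP against the reference, another called probe of Klf2 had the opposite sign. The median was 0.28 within slide 1, which held replicate 1 of both groups (35 of 43 members higher). Between the replicate 2 arrays it was 0.28 (30 of 43). With scan day as a block, which here and below sets dox+TCP replicate 1 alone against the dox arrays, the median was 0.16. Without dox replicate 1 it was 0.08 (camera adjusted p = 0.267), without dox replicate 2 0.41 and without dox+TCP replicate 1 0.34, and it was 0.04 under median centring (camera adjusted p = 0.0202). Two-cell-like genes had a median of 0.30 (camera adjusted p = 0.0113; adjusted p = 0.408 with an estimated correlation), 0.30 within slide 1, 0.49 between the replicate 2 arrays and 0.37 with scan day as a block. It was 0.60 without dox+TCP replicate 1, 0.52 without dox replicate 2 (camera adjusted p = 0.0937) and 0.16 in Cy5 alone, and did not pass with the local backgrounds as read (camera adjusted p = 0.237). 3 of the 12 passed adjusted over the list alone, and Zscan4c (1.08), Tcstv1 (1.06) and Tcstv3 (1.02) had the highest values among those named. Germline genes had a median of 0.27 (camera adjusted p = 0.00359; adjusted p = 0.709 with an estimated correlation), 0.17 within slide 1, 0.28 between the replicate 2 arrays and 0.44 with scan day as a block, with Hormad1 at 1.01 and Taf7l at 0.78. Without dox replicate 1 the germline median was 0.44, without dox replicate 2 it was 0.01 (camera adjusted p = 0.326), and without dox+TCP replicate 1 it was 0.17 (camera adjusted p = 0.0624).

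Epithelial genes had a median of −0.34 (camera adjusted p = 2.58e-07; adjusted p = 0.408 with an estimated correlation), with Ap1m2 at −1.46, the splicing factor gene Esrp1 at −1.44, Cldn7 at −0.92 and Grhl2 at −0.83, none past the threshold. The median was −0.54 within slide 1 (4 of 34 members higher), −0.13 between the replicate 2 arrays (7 of 34), −0.16 with scan day as a block, −0.13 without dox replicate 1 (camera adjusted p = 0.0514) and −0.51 without dox replicate 2. This list was brighter in the reference of replicate 2, by a median of 0.477. The fibroblast markers of feeder cells stood 0.31 higher within slide 1 (24 of 28 members) and 0.0031 higher between the replicate 2 arrays (14 of 28). Their pooled median of 0.09 (camera adjusted p = 0.0996) was −0.072 without dox replicate 1 and 0.37 without dox replicate 2 (camera adjusted p = 5.63e-07, the lowest in a range up to 0.839). Genes of LSD1 and its partner complexes had a median of −0.13 (camera adjusted p = 9.14e-05; adjusted p = 0.408 with an estimated correlation), with Mbd2 at −0.67, Ctbp1 at −0.66 and Hdac1 at −0.53. Their median was −0.15 within slide 1, −0.20 between the replicate 2 arrays and −0.17 with scan day as a block, with 8 of 30 members higher in each pair. It was −0.28 without dox replicate 1, −0.29 under median centring and −0.048 with the local backgrounds as read.

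The p53 response had a median of 0.17 (camera adjusted p = 0.0269; adjusted p = 0.408 with an estimated correlation), 0.20 in each replicate pair and 0.21 with scan day as a block, with Pmaip1 at 1.18, Mdm2 at 0.82 and Ccng1 at 0.81. Under median centring it was 0.10 (camera adjusted p = 0.185), and without dox replicate 2 or dox+TCP replicate 1 the camera adjusted p was 0.104 and 0.0808. The interferon response had a median of 0.20 (camera adjusted p = 0.043; adjusted p = 0.408 with an estimated correlation), 0.16 within slide 1, 0.08 between the replicate 2 arrays and 0.19 with scan day as a block (camera adjusted p = 0.0669), with B2m at 1.09. Its camera adjusted p was 0.0522 with the replicate number as a block, 0.0808 without dox+TCP replicate 1 and 0.616 without dox replicate 1, where the median was 0.07, and the call was lost in 11 of 24 alternatives. Cell cycle genes had a median of −0.08 (camera adjusted p = 0.0457; adjusted p = 0.709 with an estimated correlation), −0.13 within slide 1 and −0.06 between the replicate 2 arrays, and this turned to 0.02 with scan day as a block (camera adjusted p = 0.416) and without dox replicate 1. Without dox replicate 2 it was −0.21, and −0.24 under median centring.

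Camera called 8 of the 23 lists, 5 higher and 3 lower, and 0 with an estimated correlation. Over the alternatives run, the adjusted p of the set test ranged from 3.99e-05 to 0.61 for pluripotency genes, from 6e-15 to 0.748 for epithelial genes and from 2.95e-05 to 0.709 for germline genes. It ranged from 0.000842 to 0.408 for two-cell-like genes, from 0.00158 to 0.408 for the p53 response, from 0.0099 to 0.616 for the interferon response and from 0.000613 to 0.881 for cell cycle genes. The lists that did not pass limma's camera included trophoblast genes (−0.12, camera adjusted p = 0.362, turning to 0.30 without dox replicate 1 and −0.65 without dox replicate 2), primitive endoderm (0.11, 0.0518), sterol synthesis (0.21, 0.0518), glycolysis and hypoxia (−0.11, 0.0761), the fibroblast markers of feeder cells (0.09, 0.0996) and mesenchymal genes (0.16, 0.102). Leaving out 1 array moved these values. Without dox replicate 2 trophoblast genes (camera adjusted p = 0.00183), primitive endoderm (0.27, 0.0118) and mesenchymal genes (0.41, 0.000613) passed, and glycolysis and hypoxia stood at −0.0010 and sterol synthesis at 0.092. Without dox+TCP replicate 1 trophoblast genes (−0.45, 0.00566), primitive endoderm (0.16, 0.0232), sterol synthesis (0.19, 0.0301), glycolysis and hypoxia (−0.18, 0.0259) and fibroblast markers (0.20, 0.0407) passed. Without dox replicate 1 glycolysis and hypoxia passed (−0.13, 0.0323), mesenchymal genes turned to −0.073, and primitive endoderm stood at 0.064. Without dox+TCP replicate 2 trophoblast genes turned to 0.20 and glycolysis and hypoxia stood at −0.047 and sterol synthesis at 0.12. The adjusted p of the set test ranged from 6.68e-05 to 0.985 for trophoblast genes, from 0.0118 to 0.686 for primitive endoderm, from 0.00892 to 0.408 for sterol synthesis, from 0.00866 to 0.864 for glycolysis and hypoxia and from 0.000613 to 0.793 for mesenchymal genes. In the mesenchymal list 2 genes passed adjusted over the list alone, with Zeb1 at 1.28 and Snai2 at 0.86 among its highest values. Monoamine metabolism, to which the other usual targets of tranylcypromine belong, had a median of 0.07 (camera adjusted p = 0.911). It ran from 0.014 without dox replicate 1 to 0.056 without dox+TCP replicate 2 on leaving out 1 array, and turned to −0.049 under median centring and −0.034 in Cy5 alone, and the list did not pass in any alternative run (adjusted p from 0.49 to 0.996).

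**Figure D3:**
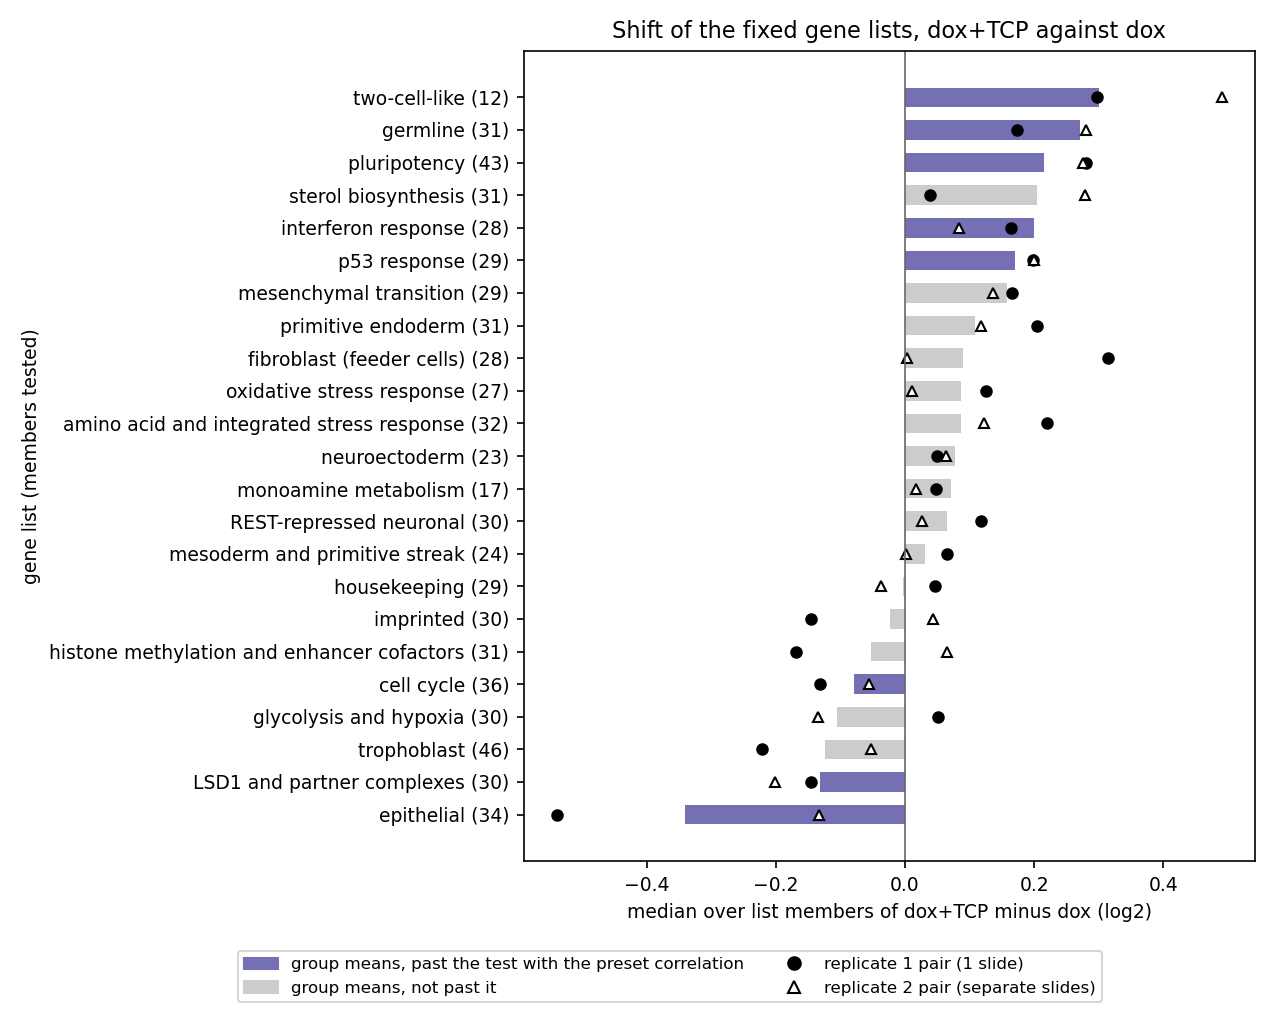
The median log2 difference of dox+TCP minus dox is plotted for each fixed list, beside the difference within slide 1 and between the replicate 2 arrays. The pluripotency list lies at 0.21, 0.28 and 0.28, and the epithelial list at −0.34, −0.54 and −0.13.

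Genes with a low or high ratio on 1 dox array were also followed on the other arrays, with no test. Of genes at least 2-fold lower on dox replicate 1, 1305 in number, the median log2 ratio was −1.20 on dox replicate 2 and −1.27 and −0.97 on the dox+TCP arrays. For the 2124 genes chosen on dox replicate 2 it was −0.65 on dox replicate 1 and −0.92 and −0.94 on the dox+TCP arrays. Averaged over both ways, dox+TCP differed from the held-out dox array by a median of −0.063 for genes chosen as lower (−0.194 and 0.067 the 2 ways) and 0.138 for genes chosen as higher (0.115 and 0.160). Between single arrays these differences ran from −0.223 to 0.253 and from −0.036 to 0.345. Deviations of same-numbered arrays correlated at 0.472 across genes in log2 ratios. Genes chosen on 1 dox array can therefore lie further from 0 on its same-numbered dox+TCP array than on the held-out dox array. Holding out an array does not remove this, so the differences cannot be read as an effect of TCP.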

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

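The tests of explanations in this part were chosen after the result was seen, apart from the test of undifferentiated cells left with TCP. Leaving out 1 array and an estimated correlation were planned for the lists, and Cy5 alone for the counts of genes and not for the lists. Patterns found and tested on the same arrays are hypotheses.

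Trophoblast ratios were lower on the replicate 2 arrays, by a median of −0.512 over 46 genes. A weaker response of the treated cells accounted for little of it, since 15.8% of the variation across members went with the Cy5 difference. Compressed ratios are argued against by the pluripotency list, whose replicate 2 ratios followed those of replicate 1 with a slope of 0.913, against 0.341 for the trophoblast list. A candidate explanation is that trophoblast transcripts were already high in the reference cells of the replicate 2 arrays: 89.2% of the variation went with the Cy3 difference, and Krt8 and Krt18 stood at 16.45 and 16.10 there on dox replicate 2 against 13.03 and 12.87 on dox replicate 1. The design names no group that separates the replicates, so no biological explanation was tested.

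Pluripotency genes were higher with dox+TCP than with dox, a weak pattern, with 0.08 without dox replicate 1 (camera adjusted p = 0.267) and adjusted p = 0.408 with an estimated correlation, in a range from 3.99e-05 to 0.61. The reference channels cannot be told apart from other causes: the median shift in Cy5 alone was 0.16 (limma camera adjusted p = 0.000183), 0.30 between the replicate 1 arrays and 0.12 between the replicate 2 arrays, and the dox replicates themselves differed by 0.28 there. Slide and scan day cannot be told apart either, since the difference of 0.28 within slide 1 (35 of 43 members higher) sets 1 array against 1 array. More undifferentiated cells left with TCP cannot be told apart from other causes. An extra share of 2.13%, estimated from Pou5f1, gave a predicted shift of 0.12 (3.15% and 0.17 at 1 SE more), against 0.28 observed in each pair. That estimate counts only cells that kept Pou5f1 at the reference level. Doxycycline shuts off the Pou5f1 transgene itself, so undifferentiated cells that had lost it are missed and the share sets no limit on them. An effect of TCP on these genes stays open and was not tested apart from these causes.

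Epithelial genes were lower with dox+TCP, a call lost with an estimated correlation (adjusted p = 0.408) and without dox replicate 1 (−0.13, camera adjusted p = 0.0514), in a range from 6e-15 to 0.748. The reference channels as the whole cause are argued against by a shift of −0.46 in Cy5 alone (limma camera adjusted p = 6e-15, which does not measure the spread over 2 arrays per group). Replicates of a group differed there by medians of 0.17 and 0.28. Each dox+TCP array stood below each dox array in Cy5, by −0.68 to −0.12. The −0.12, of dox+TCP replicate 2 against dox replicate 1, was smaller than the differences between replicates. More fibroblasts would dilute the pluripotency list, which stood at 0.21 and did not fall. That shift was itself weak and of unsettled cause, and a separate rise could hide dilution, so it cannot decide this explanation. The fibroblast list (0.09) stood at 0.31 within slide 1 (24 of 28 members higher), beside −0.54 for epithelial genes. It stood at 0.0031 beside −0.13 in replicate 2. Weaker trophoblast differentiation with TCP cannot be told apart from other causes: the trophoblast list stood at −0.12 in the ratios (camera adjusted p = 0.362) and −0.26 in Cy5 alone (6.68e-05). In the ratios, which also hold the reference difference between the replicates, it ran from −0.65 without dox replicate 2 to 0.30 without dox replicate 1. In Cy5 each dox+TCP array stood below each dox array, by medians from −0.29 to −0.18. Replicates of a group differed there by −0.097 (dox) and 0.14 (dox+TCP). The 31 epithelial genes that are not on the trophoblast list had a median of −0.33, and an effect of TCP itself stays open and untested.

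In the reference channel, 2 of 23 lists had 1 array far from the other 3 relative to the range of the 4. Chance gives about 1 in 20 lists if arrays are independent, but Cy3 deviations of same-numbered arrays correlated at 0.610 across genes. Dox replicate 2 was lowest for neuroectoderm genes, with a gap of 0.879 of the whole range, and highest for housekeeping genes, with a gap of 0.842. The ranges were small: its median log2 Cy3 level was 7.838 against 7.969 to 7.987 on the other arrays for neuroectoderm genes. For housekeeping genes it was 14.53 against 14.34 to 14.37. Spike-in controls, outside the comparisons, had a median log2 ratio of −0.39 on dox+TCP replicate 1 and 1.37 on replicate 2, above −1.07 and −2.06 on the dox arrays, over 10 kinds of 32 spots each.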

How the results depend on the processing

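The limits on local backgrounds, that of the main fit included, were chosen after the data were seen. The backgrounds as read were the setting of the planned design, and the other alternatives were planned for the counts of genes. For the lists, the mean of a gene's probes, spots with scanner warnings kept, an intensity trend, series matrix values, blocks by slide or scan day, Cy5 alone and 1 group's arrays alone were added after the data were seen. With local backgrounds as read, the wording of the planned design, limma called 0 genes in each comparison (1811, 1908 and 459 at an unadjusted p under 0.05), where replacing bright backgrounds gave 3122, 3297 and 0. Limits of 5 and 10 times the median gave 3047 and 3152 genes with dox and 3347 and 3335 with dox+TCP, and no background subtraction gave 3172 and 3127. As read, the pluripotency list stood 0.18 higher with TCP (limma camera adjusted p = 0.237). Median centring called 6021 and 5109 genes against the reference, a 2-fold minimum 1498 and 1476, and scan day as a block 0 and 0. The dox arrays alone gave 0 (5138 at an unadjusted p under 0.05) and the dox+TCP arrays alone 5936. Leaving out 1 array gave 0 to 4126 genes with dox and 0 to 5936 with dox+TCP: dox counted 4126 without dox replicate 1, 2073 without dox replicate 2 and 0 without dox+TCP replicate 1 or 2, and dox+TCP counted 5936 without either dox array and 0 without dox+TCP replicate 1 or 2. Between dox+TCP and dox the count was 0 in each setting.

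Camera called 11, 11 and 8 lists in the 3 comparisons, 0, 0 and 0 with an estimated correlation and fry 6, 6 and 0. The setting with an estimated correlation rests on 2 residual degrees of freedom. Its counts of 0 therefore do not show that correlation between genes undid the calls. Leaving out 1 array gave 5 to 12 lists between dox+TCP and dox, 5 of them without dox replicate 1. The pluripotency shift of 0.21 with TCP had camera adjusted p = 0.408 with an estimated correlation and fry adjusted p = 0.61 (range 3.99e-05 to 0.61), and ran from 0.078 (without dox replicate 1, camera adjusted p = 0.267) to 0.414 without 1 array. Median centring turned the cell cycle list with dox to 0.25 and Mcm2 to 0.055. The cell cycle shift with TCP turned to 0.024 without dox replicate 1, in a range from −0.21 to 0.024 on leaving out 1 array, and stood at −0.24 under median centring. Apart from the 2-fold minimum, which keeps fewer genes by construction, the cause was not tested.

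Deviations of same-numbered arrays correlated at 0.472 across genes in log2 ratios, 0.501 in Cy5 and 0.610 in Cy3, and replicate 1 of both groups shared a slide. The labels do not say that a number marks a shared batch and there are 2 pairs, so pairing was not assumed. The replicate block gave 0 genes (1623 unadjusted) and 8 lists, with 1 call of the main fit lost and 1 gained. Signal limits dim genes: 68.8% to 78.1% of spots per array and channel were well above background, and only probes above it on every array and channel gave 2992, 3113 and 0 genes.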

Other observations

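Some members of the cell cycle list, chosen after their values were seen, differed between the dox replicates, and others did not. Mki67, a proliferation marker, stood at 0.31 on dox replicate 1 and −2.29 on dox replicate 2 (log2 ratio to the reference), and at −0.83 and −1.32 on the dox+TCP arrays. The kinetochore gene Cenpe (0.04 and −2.57 with dox) and the spindle motor gene Kif11 (0.09 and −1.73) also differed. The mitotic kinase genes Aurka (−0.34 and −0.21) and Plk1 (−0.28 and −0.14) differed little, and Aurkb (0.13 and 0.95) went the other way. Over the fixed list the medians were −0.21 and −0.63, and neither Mki67, Cenpe nor Kif11 passed limma's test in any of the 3 comparisons.

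In the reference channel, the fibroblast markers of feeder cells and the mesenchymal genes were dimmer on the replicate 2 arrays, by medians of −0.570 and −0.472 on the log2 scale, with 6 of 28 fibroblast markers brighter there. Sct, a hormone gene on the trophoblast list, stood at 11.26 and 11.25 (normalized log2 Cy3 intensity) on the replicate 1 arrays and 15.33 and 15.11 on the replicate 2 arrays. The trophoblast homeobox gene Rhox6 stood at 11.88 and 12.05 against 14.98 and 15.08. Both were chosen after their values were seen. The pluripotency list differed by a median of −0.108 between the same channels.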
